A study of Mus musculus with 24 samples.

How the data were processed

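The arrays measured messenger RNA in cultured neurons of Npas4 wild-type (WT) and Npas4 knockout (KO) littermate mice of the C57Bl/6 strain. Npas4 is a transcription factor of the basic helix-loop-helix PAS family whose gene is switched on by neuronal activity. Per the labels' protocols, cells came from mouse embryos at embryonic day 14, either from the medial ganglionic eminence (MGE), which gives rise to inhibitory neurons, or from the cortex (CTX), whose neurons the series title treats as excitatory. The labels give 10 days in culture, and the series description gives 9 days before the overnight silencing. Activity was silenced overnight with tetrodotoxin, which blocks sodium channels, and AP-5, which blocks NMDA receptors, and the cells were then depolarized with 55 mM KCl for 0, 1 or 6 h. Per the labels' protocols, 100 ng of total RNA was amplified with NuGEN Ovation V2 and hybridized to an Affymetrix mouse genome array.

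The authors deposited one intensity per probe set and array on a linear scale, from 6.61 to 29464 across 45101 probe sets and 24 arrays, and the submitters' processing notes name RMA without a version. RMA corrects background, brings arrays to a common distribution and summarizes each probe set, and whether both cell types were normalized together is not stated. Array medians lay between 115 and 121. A normalization of this kind gives arrays similar medians, so a shift shared by most genes would not be visible. Intensities were converted to log2 here, and no other scaling was applied.

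Of the 45101 probe sets, 35890 had a gene symbol in the annotation used here, of which 34958 named 1 gene and 932 several, and 9211 had none. Gene names were compared with RefSeq (GRCm38.p6) through Entrez identifiers. This matched 34754 probe sets and changed 0 symbols. Each of 18194 genes was represented by its probe set with the highest mean over the 24 arrays, which mattered for the 9012 genes with several. A gene was tested if its probe set was above the array median in at least 2 arrays, which left 12378 genes and removed 5816. Probe sets with no gene symbol or several were tested separately. RefSeq positions were used only to find genes near Npas4.

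The labels put the 24 arrays into 12 groups of 2, by cell type, genotype and time. Tests used limma 3.58.1 in R 4.3.3 with 12 group means fitted to all 24 arrays, 12 residual degrees of freedom and 2.408 prior degrees of freedom, so all groups shared one estimate of the spread per gene. Tests were two-sided with Benjamini-Hochberg adjustment over the 12378 genes, and a gene was called at an adjusted p under 0.05. The 21 comparisons were the response to depolarization in WT cultures of each cell type, KO against WT at each time, the genotype by depolarization interactions, MGE against CTX in WT cultures at 0 h, the cell type by depolarization interactions, the cell type by genotype interaction at 6 h, and KO against WT averaged over times and cell types. Errors beside log2 changes are standard errors (SE) from these fits, and the number of arrays limits the precision.

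A set of 22 gene lists was drawn up from general knowledge: rapid response, late response, negative feedback, neuropeptides, growth factors, glutamate receptors, GABA receptors, potassium channels, bHLH-PAS factors, Npas4 targets named in other studies, cholesterol synthesis, stress, sex-linked genes, erythroid genes, and markers of interneurons, excitatory neurons, astrocytes, oligodendrocytes, microglia, vascular cells, progenitors, and striatal or cholinergic neurons. Lists with at least 3 measured genes were compared with all other genes by limma's camera, with a preset correlation of 0.01 between genes and adjustment over the lists of each comparison. Of the erythroid list, 1 gene was measured, so the list was not tested. The 62 camera calls made without the replicate block were repeated with the correlation estimated from the data. With that estimate 9 of 62 calls held: rapid response in MGE cultures at 1 h, rapid response, late response and feedback in CTX cultures at 1 h and again at 6 h, growth factors in CTX cultures at 6 h, and excitatory markers in MGE against CTX. With the block described below and an estimated correlation together 24 of the 62 held, and 0 of 28 calls made only with the block.

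Gene lists, comparisons, alternatives and the rule for named genes were fixed before the data were examined. Under that rule the genes eligible to be named were Npas4 in every comparison, up to 10 called genes with the largest rise and 10 with the largest fall whose arrays did not overlap, up to 4 called members of each list or else its 2 largest as values, and Fos, Fosb, Egr1, Arc, Nr4a1, Bdnf, Nptx2, Sst, Homer1, Plk2, Mdm2 and Syt10 anywhere. Where 5 or fewer genes were called all were eligible, and genes with Riken, Gm or predicted names were counted and not named. The text names a selection of these. A gene outside the rule is said to have been chosen after its values were seen. Induced genes were those that rose at least 2-fold with an adjusted p under 0.05 in WT cultures.

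The labels give replicate numbers (repeat 1 and repeat 2) but do not say that these were separate cultures or animals, so p-values measure only the spread between these arrays. That spread may be technical in CTX cultures. The vascular marker list, however, averaged log2 6.55 to 6.87 in CTX repeat 1 and 7.72 to 8.73 in CTX repeat 2 arrays. The astrocyte list averaged 10.24 to 10.58 in CTX KO repeat 1 and 9.42 to 9.87 in CTX KO repeat 2 arrays, but overlapped between repeats in CTX WT. Part of the CTX spread may therefore not be technical. In MGE cultures sex-linked genes argue against purely technical repeats. Eif2s3y, a Y-linked gene, was at log2 9.38 to 9.87 in KO repeat 1 and 11.16 to 11.48 in KO repeat 2. Xist was at 10.79 to 11.99 in WT repeat 1 and 8.25 to 10.05 in WT repeat 2. Whether same-numbered arrays deviated together was checked over the 15 pairs of groups of each cell type. In CTX cultures all 15 correlations were above 0.1 (lowest 0.11, median 0.37, highest 0.71), and a fit with the replicate number as a block (10 residual degrees of freedom) is given beside a CTX result where it changed the call or moved a count by over 1.5 times. In MGE cultures 13 of 15 were above 0.1 (lowest -0.23, median 0.61, highest 0.86). As not all were, the numbers were not taken to pair those arrays, though the median was higher than in CTX cultures. Counts with the block are also given for KO against WT and for induced genes in MGE cultures at 6 h.

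The alternatives tried were the mean of a gene's probe sets, no filter, cyclic loess between arrays, limma-trend, a separate fit per cell type, the replicate block, leaving out each array in turn, the estimated correlation for lists, and, for induced genes, a set chosen on the mean of WT and KO and a set with no fold minimum. KO arrays in place of WT arrays, the rapid response list without Npas4, and the block with an estimated correlation were added after seeing the data. No deposited column was left out.

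The tests were run on simulated data with 200 of 12378 genes changed. At 2-fold, 55.5% of changed genes were recovered for the MGE response at 6 h, 60% for KO against WT in CTX cultures at 6 h, 41% for the genotype interaction in MGE cultures at 6 h, 24% for the cell type interaction at 6 h and 93% for KO against WT averaged over all groups. At 4-fold these were 91%, 93%, 86%, 82.5% and 100%. At 1.41-fold they were 8.5%, 13.5%, 0%, 0% and 71.5%. In a simulated KO against WT comparison in CTX cultures at 6 h, a list of 15 genes shifted by 0.5 had a camera adjusted p of 1e-20, and 1 of 20 unshifted lists was called. The simulated noise was independent between genes and between arrays, whereas same-numbered arrays deviated together in the real data. These figures therefore do not show how the tests behave with correlated genes or arrays.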

Results

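Messenger RNA was measured on 24 arrays from neuron cultures of Npas4 WT and KO littermate mice, 2 arrays in each of 12 groups. Cultures derived from the MGE or from the cortex (CTX) were silenced overnight and depolarized with KCl for 0, 1 or 6 h. The series asks which activity-induced genes depend on Npas4 in inhibitory and in excitatory neurons. Array medians lay between 115 and 121 intensity units, and 12378 genes were tested. The 2 arrays of a group correlated at 0.965 to 0.992 across genes in 11 groups and at 0.951 in MGE WT at 0 h. In that group 1507 genes lay over 2-fold apart between the arrays, against 116 to 980 in the other groups.

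Npas4, the targeted gene, was near its lowest level in every array at 0 h and rose strongly only in WT cultures. Its log2 intensity in the 2 arrays of each group was 5.70 and 5.84 in MGE WT at 0 h, 12.04 and 11.20 at 1 h, and 9.32 and 8.59 at 6 h. In MGE KO it was 5.67 and 5.35, then 7.35 and 7.0, then 7.07 and 6.80. In CTX WT it was 5.80 and 5.94, then 12.03 and 11.77, then 11.73 and 11.84. In CTX KO it was 5.82 and 5.78, then 6.80 and 6.85, then 7.76 and 7.82. The remaining KO signal rose by log2 1.66 ± 0.25 (SE, n = 2 arrays per group) at 1 h (limma, adjusted p = 0.0052) and 1.43 ± 0.25 at 6 h (adjusted p = 0.0013) in MGE cultures. In CTX KO cultures it rose by 1.98 ± 0.25 at 6 h (adjusted p = 2.8e-05), and the change at 1 h was 1.02 ± 0.25 (adjusted p = 0.081). Whether the probe set lies in the deleted part of the gene is not settled, so its signal in KO arrays does not show whether functional Npas4 remained.

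**Figure D1:**
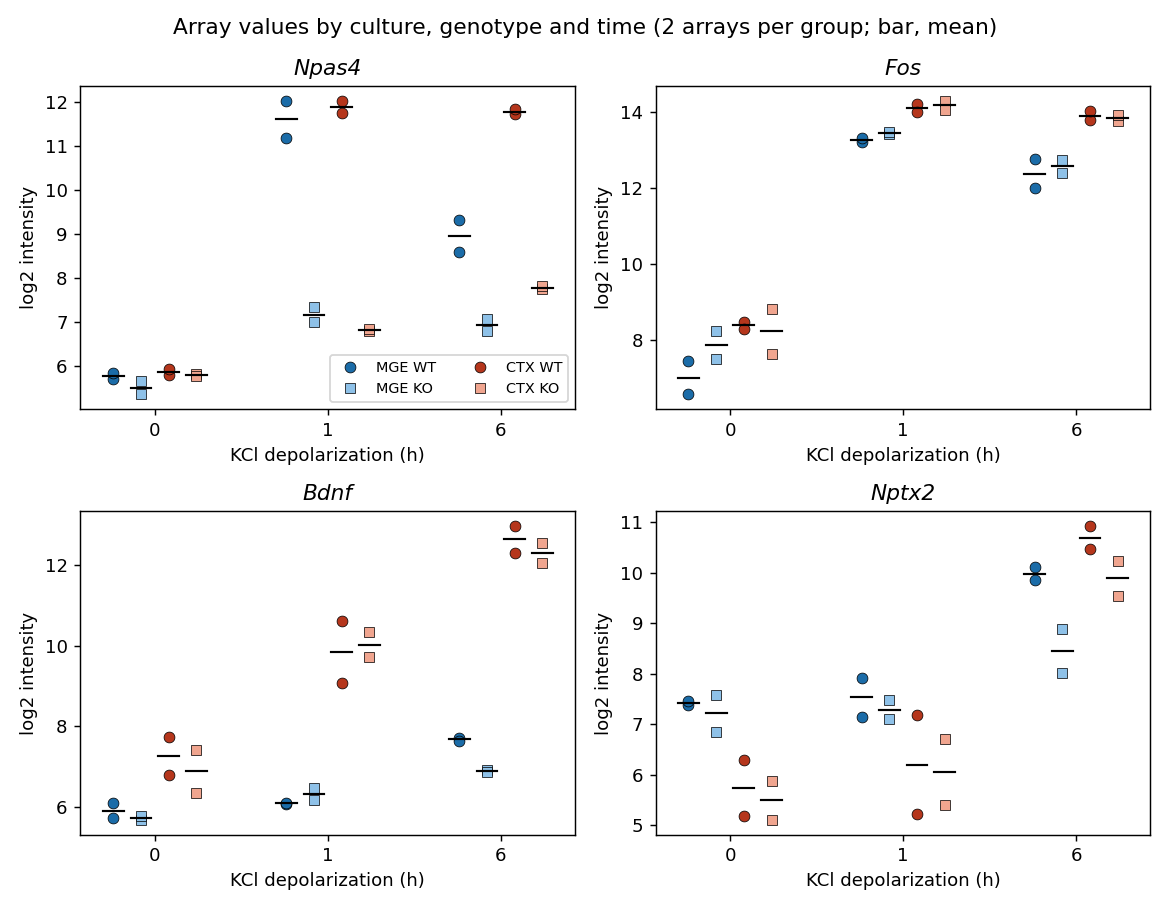
Log2 intensity of Npas4, Fos, Bdnf and Nptx2 in each array (points) at 0, 1 and 6 h of depolarization, by cell type and genotype, with bars at the mean of 2 arrays. Npas4 reached 11.62 in MGE WT and 11.90 in CTX WT at 1 h, against 7.17 and 6.82 in KO, whereas Fos reached 13.26 and 14.09 in WT and 13.44 and 14.17 in KO.

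The cell types were compared at rest in WT cultures at 0 h. Genes of excitatory cortical neurons were far lower in MGE cultures. The excitatory list averaged log2 6.55 and 6.42 in the MGE arrays, below the array median. Such levels were not shown to be above background, so folds against them are approximate. Neurod6, a transcription factor of cortical projection neurons, was 391-fold lower (log2 -8.61 ± 0.20, SE, n = 2 per group, adjusted p = 1.3e-12). Tbr1 was 224-fold lower (-7.81 ± 0.27) and Neurod2 was 121-fold lower (-6.91 ± 0.22). Of 12 measured excitatory markers, 10 were lower and 1, the upper layer transcription factor Cux2, was higher (log2 1.29 ± 0.17, named after its values were seen), with 11 lower and 1 higher when adjusted over the list alone. The excitatory list had a mean of -4.72 (camera adjusted p = 3e-07). Genes of MGE-derived interneurons were higher. Npy, a neuropeptide, was 19.7-fold higher (4.30 ± 0.22) and Slc32a1, the vesicular GABA transporter, 11.1-fold (3.47 ± 0.30). Lhx6, an MGE transcription factor, was 8.98-fold higher (3.17 ± 0.28) and Sst, somatostatin, 5.18-fold (2.37 ± 0.29, adjusted p = 1.4e-05). Of 17 interneuron markers, 15 were higher and 1, the calcium-binding protein Calb2, was lower (-2.39 ± 0.49, named after its values were seen), the same counts as when adjusted over the list alone. The interneuron list had a mean of 2.09 (adjusted p = 4.6e-06, adjusted p = 0.35 with an estimated correlation).

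Among all genes the highest in MGE cultures were Hapln1, a link protein of the extracellular matrix (49.3-fold, log2 5.62 ± 0.27), and Lhx8, a transcription factor of the ventral forebrain (46.8-fold, 5.55 ± 0.78). Of 10 cholesterol synthesis genes, 9 were lower in MGE cultures, also when adjusted over the list alone, including Lss (-1.50 ± 0.23) and Idi1 (-1.23 ± 0.19). Their list mean was -0.72 (adjusted p = 0.0045, adjusted p = 0.81 with an estimated correlation). Among the genes eligible to be named in any comparison, single ones went both ways at rest. Nr4a1 was 3.30-fold lower (-1.72 ± 0.23), Homer1 was 2.66-fold lower (-1.41 ± 0.18) and Plk2 was 8.16-fold lower (-3.03 ± 0.41) in MGE cultures. Nr4a1 lay below the array median in MGE (log2 4.60) and in CTX cultures (6.32), so its fold is approximate. Arc (0.96 ± 0.34, adjusted p = 0.023) and Nptx2 (1.69 ± 0.60, adjusted p = 0.023) were higher in MGE cultures, though Arc lay below the array median in MGE (6.37) and CTX cultures (5.41), and Nptx2 in CTX cultures (5.73). Neither passed without MGE WT 0 h repeat 1 (0.93 and 1.73) or 2 (1 and 1.66). Arc also did not pass without CTX WT 0 h repeat 1 (0.84) or with cyclic loess (0.80), nor Nptx2 without CTX WT 0 h repeat 2 (1.14). Npas4 did not pass (-0.10, adjusted p = 0.74). In total 4295 genes were higher and 3653 lower in MGE cultures.

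Lists of markers of other cells did not pass between the cell types, though some members did. Both MGE arrays lay above both CTX arrays in the mean level of the microglia, progenitor and oligodendrocyte lists. Of 8 microglia markers 4 were higher in MGE cultures (list mean 1.12, adjusted p = 0.37), among them Tyrobp (2.43 ± 0.56). Of 9 progenitor markers 3 were higher and 1 was lower (mean 1.11, adjusted p = 0.37), with Nes at 2.89 ± 0.55. Of 5 oligodendrocyte markers 2 were higher (mean 0.92, adjusted p = 0.37), with Cnp at 2.01 ± 0.18. Adjusting over each of these lists alone gave the same counts. Means were 0.19 for astrocyte markers (adjusted p = 0.96), -0.33 for vascular markers (adjusted p = 0.89), 0.93 for striatal or cholinergic markers (adjusted p = 0.82) and -1.32 for 4 sex-linked genes (adjusted p = 0.41). Hba-a2, the 1 erythroid gene measured, was 5.41-fold lower in MGE cultures (-2.43 ± 0.37). For 4 genes, Glul, Hif1a, Nr4a2 and Egr3, another probe set of the gene passed in the opposite direction here.

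Depolarization for 1 h raised the transcription factors of the immediate early response in MGE WT cultures. Nr4a1 rose 152-fold (log2 7.25 ± 0.23, SE, n = 2 per group, adjusted p = 9.8e-11). Fosb rose 91.3-fold (6.51 ± 0.43), Fos rose 75.5-fold (6.24 ± 0.36), Npas4 rose 57.8-fold (5.85 ± 0.25) and Egr2 rose 30.5-fold (4.93 ± 0.27). At 0 h Nr4a1 (log2 4.60), Fosb (4.96) and Npas4 (5.77) lay below the array median. Detection calls were not used here, so such levels were not shown to be above background and folds against them are approximate here and below. Arc, a synaptic protein, rose by 3.47 ± 0.34 and Egr1 by 2.65 ± 0.21. Of 22 rapid response genes 17 rose and none fell, with 19 rising when adjusted over the list alone (mean 3.22, camera adjusted p = 5.5e-78). Bdnf, a neurotrophin, changed by 0.19 (adjusted p = 0.93) and Nptx2, a synaptic pentraxin, by 0.11, neither passing. Among genes that fell were Zfp691, a zinc finger gene (2.99-fold lower, -1.58 ± 0.22), and Wdr38 (2.73-fold lower, -1.45 ± 0.17).

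Other lists moved less in MGE cultures at 1 h. Of 16 feedback genes 3 rose, also over the list alone, with Dusp1, a phosphatase of MAP kinases, at 1.15 ± 0.13 (list mean 0.64, adjusted p = 9.2e-06, adjusted p = 0.17 with an estimated correlation). Of 10 cholesterol genes 2 rose, and 5 when adjusted over the list alone (mean 0.41, adjusted p = 2.6e-06, adjusted p = 0.18 with an estimated correlation). Of 19 late response genes 1 rose, and 2 when adjusted over the list alone (mean 0.46, adjusted p = 0.0014, adjusted p = 0.42 with an estimated correlation). In total 48 genes rose and 23 fell. The 71 calls became 1813 without MGE WT 0 h repeat 1, 34 without repeat 2 of that group, 31 without MGE WT 1 h repeat 1 and 21 without its repeat 2. The late response list passed neither without MGE WT 0 h repeat 1 (adjusted p = 0.11) nor without MGE WT 1 h repeat 1 (adjusted p = 0.12), nor the feedback list without MGE WT 0 h repeat 1 (adjusted p = 0.091).

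In CTX WT cultures the same class of genes responded at 1 h. Fosb rose 181-fold (log2 7.50 ± 0.43, SE, n = 2 per group, adjusted p = 1.4e-07). Npas4 rose 65.4-fold (6.03 ± 0.25), Nr4a1 rose 63.2-fold (5.98 ± 0.23), Fos rose 51.7-fold (5.69 ± 0.36) and Arc rose 44.8-fold (5.49 ± 0.34). Egr1 rose 11.8-fold (3.56 ± 0.21) and Vgf, a secretory granule protein, rose 10.9-fold (3.45 ± 0.43). Of 22 rapid response genes 18 rose, and 20 when adjusted over the list alone (mean 3.68, adjusted p = 3.6e-126). Of 16 feedback genes 6 rose, and 8 rose and 1 fell over the list alone (mean 0.89, adjusted p = 5.4e-14), with Dusp1 at 1.93 ± 0.13 and Crem, a cAMP-responsive factor, at 2.20 ± 0.28. Of 19 late response genes 3 rose, and 9 when adjusted over the list alone (mean 0.86, adjusted p = 2e-12). Bdnf rose 5.96-fold (2.58 ± 0.45, adjusted p = 0.011), but did not pass without CTX WT 1 h repeat 1 (1.80) or CTX WT 0 h repeat 2 (2.10). Nptx2 changed by 0.47 ± 0.60 (adjusted p = 1).

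Of 13 stress genes in CTX cultures at 1 h, 2 rose, also over the list alone, including the heat shock co-chaperone Dnajb1 (1.37 ± 0.14, list mean 0.27, adjusted p = 2e-04, adjusted p = 0.069 with an estimated correlation). The list of Npas4 targets from other studies, with 1 of 4 risen either way, had a mean of 0.86 (adjusted p = 0.011, adjusted p = 0.14 with an estimated correlation). It did not pass without CTX WT 1 h repeat 1 (adjusted p = 0.25) or CTX WT 0 h repeat 2 (adjusted p = 0.066). The cholesterol list had a mean of 0.17 with no gene called, and 1 over the list alone (adjusted p = 0.0098, adjusted p = 0.48 with an estimated correlation), and it did not pass without CTX WT 0 h repeat 1 (adjusted p = 0.97) or CTX WT 1 h repeat 2 (adjusted p = 0.097). The neuropeptides (mean 0.29, adjusted p = 0.036) and the microglia markers (mean 0.29, adjusted p = 0.0077) also passed with the replicate block (adjusted p = 0.17 and adjusted p = 0.31 with the block and an estimated correlation). In total 77 genes rose and 30 fell, the fall of Wdr38 being 4.24-fold (-2.08 ± 0.17). The 107 calls became 50 without CTX WT 0 h repeat 1 and 38 without either its repeat 2 or CTX WT 1 h repeat 1.

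In MGE WT cultures 3128 genes had changed after 6 h, against 71 after 1 h. Fos was still 40.9-fold higher than at 0 h (log2 5.35 ± 0.36, SE, n = 2 per group, adjusted p = 7.4e-07) and Npas4 9.11-fold higher (3.19 ± 0.25, adjusted p = 1.9e-06). Rerg, a Ras-like GTPase, rose 13.9-fold (3.80 ± 0.41), Il21, a cytokine, rose 17.2-fold (4.10 ± 0.19, adjusted p = 9e-09), and Sv2c, a synaptic vesicle protein, rose 12.4-fold (3.64 ± 0.26). Nptx2 rose 5.84-fold (2.55 ± 0.60, adjusted p = 0.0072) and Bdnf rose 3.41-fold (1.77 ± 0.45, adjusted p = 0.012), but neither passed without MGE WT 6 h repeat 1 (2.42 and 1.74). Egr1 and Arc did not pass (0.14, adjusted p = 0.68, and 0.09, adjusted p = 0.88), and neither did Sst (0.23, adjusted p = 0.60). The largest named falls were those of Tha1, a threonine aldolase gene (6.56-fold lower, -2.71 ± 0.32), and Wnt7a, a secreted signalling protein (5.85-fold lower, -2.55 ± 0.24).

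By list, 12 of 22 rapid response genes were higher at 6 h than at 0 h in MGE cultures, with 12 higher and 1 lower over the list alone (mean 1.61, adjusted p = 7.5e-09, adjusted p = 0.086 with an estimated correlation). Of 19 late response genes 10 rose, and 13 when adjusted over the list alone, such as Vgf (3.05 ± 0.43) and Pcsk1, a prohormone convertase (2.76 ± 0.46). The list had a mean of 1.53 (adjusted p = 3e-08, adjusted p = 0.086 with an estimated correlation). Of 15 potassium channel genes 8 rose and 1 fell, with 9 and 1 over the list alone. Kcnn2 rose by 2.23 ± 0.40 and Kcnj4 by 1.86 ± 0.16, and the list had a mean of 0.98 (adjusted p = 2.6e-05, adjusted p = 0.11 with an estimated correlation). The one that fell was Kcnh2 (-0.88 ± 0.27, named after its values were seen), which did not pass without MGE WT 6 h repeat 1 (-1.10) or 2 (-0.67) or MGE WT 0 h repeat 2 (-0.69). The phosphatase Dusp2 fell (-1.11 ± 0.21, also named after its values were seen) among 16 feedback genes, of which 9 rose. Over the list alone the counts were the same (mean 0.99, adjusted p = 0.00053, adjusted p = 0.16 with an estimated correlation). Crem rose 11.2-fold (3.48 ± 0.28). Of 13 bHLH-PAS factors 6 rose, also over the list alone, among them the clock gene Per2 (2.59 ± 0.31, mean 0.66, adjusted p = 0.0029, adjusted p = 0.19 with an estimated correlation). Of 10 cholesterol genes 5 rose, and 6 over the list alone, with Idi1 at 1.08 ± 0.19 (mean 0.52, adjusted p = 0.00035, adjusted p = 0.19 with an estimated correlation).

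Of 5 further lists called in MGE cultures at 6 h, 4 did not pass without at least 1 of the arrays. Of 10 GABA receptor genes 4 rose, also over the list alone, including Gabra2 (1.42 ± 0.27, list mean 0.63, adjusted p = 0.018, adjusted p = 0.26 with an estimated correlation). This list averaged 9.89 in MGE WT 0 h repeat 2, against 10.3 to 10.87 in the other 5 MGE arrays of repeat 2. It did not pass without that array (adjusted p = 0.097) or without MGE WT 6 h repeat 1 (adjusted p = 0.055). Of 11 neuropeptides 3 rose, and 4 over the list alone, such as Cartpt at 2.39 ± 0.31 (mean 0.98, adjusted p = 0.012, adjusted p = 0.20 with an estimated correlation). They did not pass without MGE WT 0 h repeat 1 (adjusted p = 0.067) or MGE WT 6 h repeat 1 (adjusted p = 0.064). Of 9 growth factors 3 rose, and 4 over the list alone (mean 0.92, adjusted p = 0.012, adjusted p = 0.086 with an estimated correlation). This list did not pass without MGE WT 0 h repeat 1 (adjusted p = 0.12). Of 13 stress genes 5 rose, and 6 rose and 1 fell over the list alone, with Sesn2 at 1.82 ± 0.33 (mean 0.61, adjusted p = 0.049, adjusted p = 0.27 with an estimated correlation). The stress list did not pass without MGE WT 0 h repeat 1 (adjusted p = 0.33) or MGE WT 6 h repeat 1 (adjusted p = 0.063). The list of Npas4 targets from other studies had 2 of 4 risen, and 3 over the list alone (mean 1.40, adjusted p = 0.012, adjusted p = 0.16 with an estimated correlation). Glutamate receptors did not pass as a list (mean -0.08, adjusted p = 0.89), and Gria4 (-0.39), whose other probe set went the other way (1.11, adjusted p = 0.006), did not pass without any 1 of the 4 arrays (-0.35 to -0.43). In total 1180 genes rose and 1948 fell. The 3128 calls became 5248 without MGE WT 0 h repeat 1, 1380 without its repeat 2 and 1103 without MGE WT 6 h repeat 1.

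In CTX WT cultures 4362 genes had changed after 6 h, against 107 after 1 h. Fosb was 147-fold higher than at 0 h (log2 7.20 ± 0.43, SE, n = 2 per group, adjusted p = 6.9e-08), Serpinb2, a protease inhibitor, 76.7-fold (6.26 ± 0.29) and Pcsk1 67.2-fold (6.07 ± 0.46). Npas4 was 60.6-fold higher (5.92 ± 0.25, adjusted p = 3.8e-09), Bdnf 41.8-fold (5.38 ± 0.45, adjusted p = 1.1e-06) and Nptx2 31.0-fold (4.95 ± 0.60, adjusted p = 2.1e-05). Arc was 13.3-fold higher (3.74 ± 0.34), Egr1 7.15-fold (2.84 ± 0.21) and Sst 2.52-fold (1.34 ± 0.29, adjusted p = 0.0024). Genes for zinc finger proteins made up most of the largest falls, led by Zfp759 (14.6-fold lower, -3.87 ± 0.33), Zfp354b (13.2-fold lower, -3.72 ± 0.49) and Zfp94 (12.6-fold lower, -3.65 ± 0.27).

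Of 22 rapid response genes 19 rose in CTX cultures at 6 h, and 20 over the list alone (mean 3.11, adjusted p = 1.2e-20). Of 19 late response genes 16 rose, also over the list alone (mean 2.58, adjusted p = 2.6e-13). Of 16 feedback genes 12 rose and 1 fell, also over the list alone, with Crem at 4.13 ± 0.28 and Dusp4 at 3.65 ± 0.42 (mean 1.88, adjusted p = 1.4e-09). The one that fell was again Dusp2 (-0.80 ± 0.21), which did not pass without CTX WT 0 h repeat 1 (-0.74) or CTX WT 6 h repeat 2 (-0.65). Of 9 growth factors 4 rose, also over the list alone, including Inhba, a subunit of activin (2.20 ± 0.39, mean 1.21, adjusted p = 0.0063). Of 11 neuropeptides 6 rose, and 7 over the list alone, with Crh, corticotropin-releasing hormone, at 4.75 ± 0.84 and Penk, proenkephalin, at 1.88 ± 0.37 (mean 1.43, adjusted p = 9.8e-05, adjusted p = 0.056 with an estimated correlation). Of 13 stress genes 4 rose, also over the list alone, with Sesn2 at 2.24 ± 0.33 and Hspa1b, a heat shock protein, at 2.07 ± 0.32 (mean 0.85, adjusted p = 0.00022, adjusted p = 0.056 with an estimated correlation). The Npas4 targets from other studies had 2 of 4 risen either way (mean 2.64, adjusted p = 0.0069, adjusted p = 0.09 with an estimated correlation).

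Smaller list changes in CTX cultures at 6 h included bHLH-PAS factors, with 4 of 13 risen either way and Per1 at 2.56 ± 0.23 (mean 0.51, adjusted p = 0.029, adjusted p = 0.36 with an estimated correlation). They did not pass without CTX WT 6 h repeat 1 (adjusted p = 0.15). Cholesterol genes, with 4 risen and 1 fallen of 10 either way, had a mean of 0.35 (adjusted p = 0.0059, adjusted p = 0.36 with an estimated correlation). This mean did not pass without CTX WT 0 h repeat 1 (adjusted p = 0.069). Of 12 excitatory markers 4 fell and 1, Fezf2 (1.36 ± 0.22), rose, and the list did not pass (mean -0.11, adjusted p = 0.88). Potassium channels (mean 0.26, adjusted p = 0.13), glutamate receptors (mean -0.32, adjusted p = 0.37) and GABA receptors (mean 0.01, adjusted p = 0.52) did not pass as lists, though Kcna2 (-1.20 ± 0.23) and Gria4 (-0.68 ± 0.12) fell. Microglia markers had a mean of 0.63 (adjusted p = 0.078, 0.0091 with the replicate block, and adjusted p = 0.35 with the block and an estimated correlation). In total 1297 genes rose and 3065 fell.

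**Figure D2:**
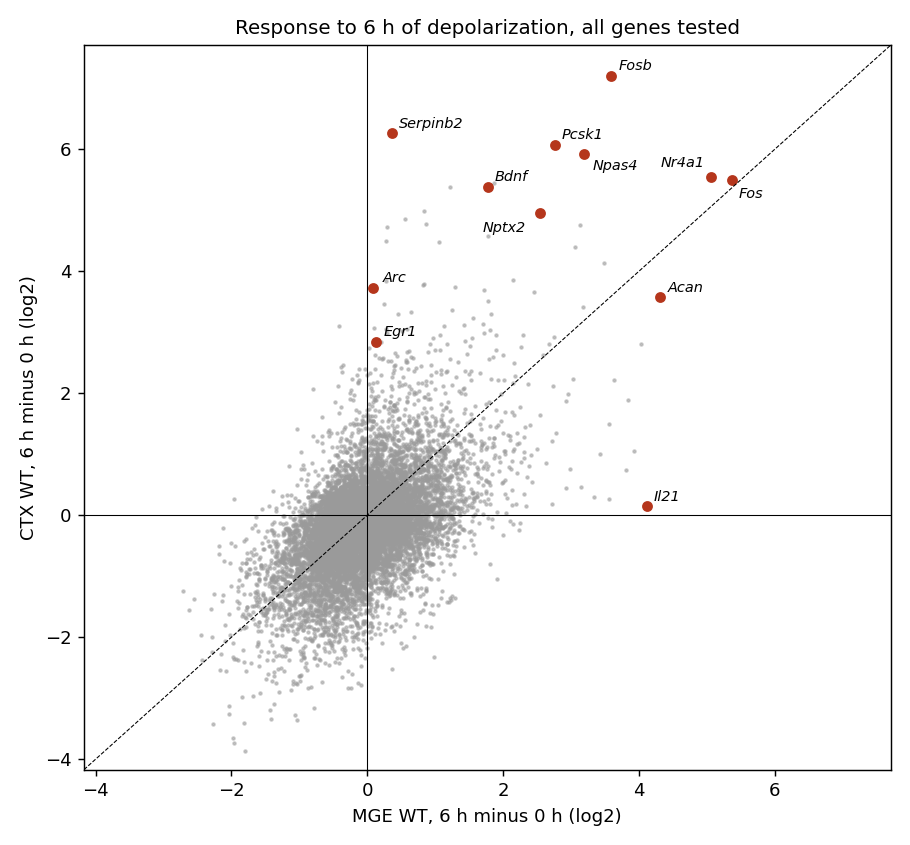
Log2 change from 0 to 6 h in WT cultures for each of 12378 genes, MGE on one axis and CTX on the other, with a dashed line of equal change. Il21 lies toward MGE (4.10 in MGE), whereas Serpinb2 (6.26 in CTX), Bdnf (5.38) and Arc (3.74) lie toward CTX.

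Between 1 and 6 h the early genes fell in MGE WT cultures. Egr2 fell 16.7-fold (log2 -4.06 ± 0.27, SE, n = 2 per group), Arc fell 10.4-fold (-3.38 ± 0.34). Npas4 fell 6.35-fold (-2.67 ± 0.25, adjusted p = 1.6e-05) and Egr1 fell 5.71-fold (-2.51 ± 0.21), while Fos did not pass (-0.88, adjusted p = 0.13). Of 22 rapid response genes 14 fell and none rose in MGE cultures, and 16 fell over the list alone (mean -1.61, adjusted p = 5e-12, adjusted p = 0.069 with an estimated correlation). Rises from 1 to 6 h included Sv2c (3.56 ± 0.26), Il21 (3.70 ± 0.19) and Cacng5, a subunit associated with AMPA receptors (3.67 ± 0.27). Of 19 late response genes 8 rose (mean 1.08, adjusted p = 3.4e-07, adjusted p = 0.077 with an estimated correlation). Of 15 potassium channels 8 rose (mean 0.93, adjusted p = 7.1e-07, adjusted p = 0.069 with an estimated correlation). Adjusted over the list alone these counts were the same. In total 506 genes rose and 1083 fell. The 1589 calls became 670 without MGE WT 1 h repeat 1, 485 without MGE WT 6 h repeat 1 and 1049 without its repeat 2.

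In CTX WT cultures Npas4 (-0.11 ± 0.25, SE, n = 2 per group, adjusted p = 0.80), Fos (-0.19, adjusted p = 0.76) and Fosb (-0.30) did not pass between 1 and 6 h. Arc fell 3.36-fold (-1.75 ± 0.34, adjusted p = 0.0014), Ier2 fell 4.12-fold (-2.04 ± 0.30) and Btg2 fell 3.88-fold (-1.96 ± 0.34). Nptx2 rose 22.4-fold (4.49 ± 0.60, adjusted p = 7.4e-05), Bdnf rose by 2.81 ± 0.45 (adjusted p = 0.00033) and Serpinb2 rose 88.6-fold (6.47 ± 0.29). Rapid response genes went both ways, with 1 risen and 8 fallen of 22 and the list did not pass (mean -0.57, adjusted p = 0.16). Of 19 late response genes 12 rose, also over the list alone (mean 1.71, adjusted p = 7.1e-10, adjusted p = 0.094 with an estimated correlation). Vascular (mean 0.38, adjusted p = 0.048) and progenitor markers (mean 0.40, adjusted p = 0.046) also passed with the replicate block (each with adjusted p = 0.48 with the block and an estimated correlation). In total 1022 genes rose and 2669 fell. The 3691 calls became 2107 without CTX WT 1 h repeat 2.

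Responses in the cell types overlapped. Of genes that changed at least 2-fold at 1 h, 26 rose in both, out of 39 in MGE and 60 in CTX cultures, against 0.189 for independent lists, and 7 fell in both. At 6 h 172 rose in both, out of 517 and 629 (26.3 for independent lists), and 338 fell in both, out of 648 and 1372 (71.8 for independent lists). Across genes, which are not independent replicates, the log2 changes correlated at r = 0.50 at 1 h and 0.53 at 6 h, with no array shared between the cell types.

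The response was compared between cell types with an interaction term in WT cultures, the signed log2 change in MGE minus that in CTX cultures. For this interaction, more or less and larger or smaller refer to the signed difference. A gene that fell less in MGE than in CTX cultures therefore counts as more. At 6 h Bdnf responded 12.2-fold less in MGE than in CTX cultures (log2 difference -3.61 ± 0.64, SE, n = 2 per group, adjusted p = 0.0035) and Arc 12.5-fold less (-3.65 ± 0.48, adjusted p = 0.00049). Egr1 responded 6.51-fold less (-2.70 ± 0.30, adjusted p = 0.00025) and Npas4 6.65-fold less (-2.73 ± 0.35, adjusted p = 0.00043). The largest difference toward CTX was that of Serpinb2 (-5.90 ± 0.41). Toward MGE cultures, the difference was positive for Il21 (15.5-fold, 3.95 ± 0.27), Cacng5 (3.29 ± 0.38) and Rspo3, a secreted Wnt agonist (3.04 ± 0.48). It was also positive for the potassium channel Kcna2 (1.99 ± 0.33), which fell in CTX cultures. Nptx2 did not pass (-2.41 ± 0.85, adjusted p = 0.08, and 0.003 with the replicate block), nor did Sst (-1.11, adjusted p = 0.094, and 0.044 with the block).

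Of 22 rapid response genes 13 responded less and 3 more in MGE cultures at 6 h, and 14 and 3 over the list alone (mean -1.50, adjusted p = 8.1e-08, adjusted p = 0.29 with an estimated correlation). For the late response list 6 of 19 responded less and 1 more, and 10 and 2 over the list alone (mean -1.04, adjusted p = 0.00027, adjusted p = 0.39 with an estimated correlation). For the feedback list 5 of 16 responded less, and 6 over the list alone (mean -0.89, adjusted p = 0.00016, adjusted p = 0.29 with an estimated correlation). With the replicate block, potassium channels (mean 0.72, adjusted p = 0.077, and 0.017 with the block) and microglia markers (mean -0.66, adjusted p = 0.20, and 0.02 with the block) also passed (each with adjusted p = 0.44 with the block and an estimated correlation). In total the signed log2 change was higher in MGE than in CTX cultures for 865 genes and lower for 485. The 1350 calls became 3901 without MGE WT 0 h repeat 1, 698 without its repeat 2, 774 and 677 without MGE WT 6 h repeat 1 or 2, 770 and 539 without CTX WT 0 h repeat 1 or 2, and 2504 without CTX WT 6 h repeat 1. In KO cultures 1345 of the 1350 genes differed between cell types in the same direction and 724 were also called.

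At 1 h 2 genes differed in response, Nr4a3, an orphan nuclear receptor, with a 5.77-fold larger rise in MGE cultures (2.53 ± 0.18, adjusted p = 9.7e-06), and Sstr2, a somatostatin receptor (1.87 ± 0.27, adjusted p = 0.044, and 0.064 with the replicate block). Bdnf at -2.39 ± 0.64 did not pass (adjusted p = 0.81, and 0.0071 with the block), and neither did Npas4 (-0.18). The lists moved by -0.45 for rapid response (1 gene larger in MGE, and 5 larger and 10 smaller over the list alone, adjusted p = 0.0071) and -0.41 for late response (2 smaller over the list alone, adjusted p = 0.011). They moved by -0.26 for feedback (3 smaller over the list alone, adjusted p = 0.027) and 0.24 for cholesterol (none over the list alone, adjusted p = 0.011). Each had adjusted p = 0.61 with an estimated correlation. None of these lists passed without CTX WT 1 h repeat 1 (adjusted p of 0.12, 0.57, 0.53 and 0.10), MGE WT 0 h repeat 1 (0.30, 0.67, 0.56 and 0.30) or MGE WT 1 h repeat 1 (0.11, 0.11, 0.37 and 0.12). Feedback and cholesterol also did not pass without CTX WT 0 h repeat 2 (adjusted p = 0.25 and 0.70). The 2 calls became 551 without MGE WT 0 h repeat 1, 3 without CTX WT 1 h repeat 2, and 1 without MGE WT 1 h repeat 1 or 2, CTX WT 0 h repeat 1 or 2 or CTX WT 1 h repeat 1. Sstr2 did not pass without either MGE WT 1 h array (1.81 and 1.93) or without any of the 4 CTX arrays (1.71 to 2.03).

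**Figure D3:**
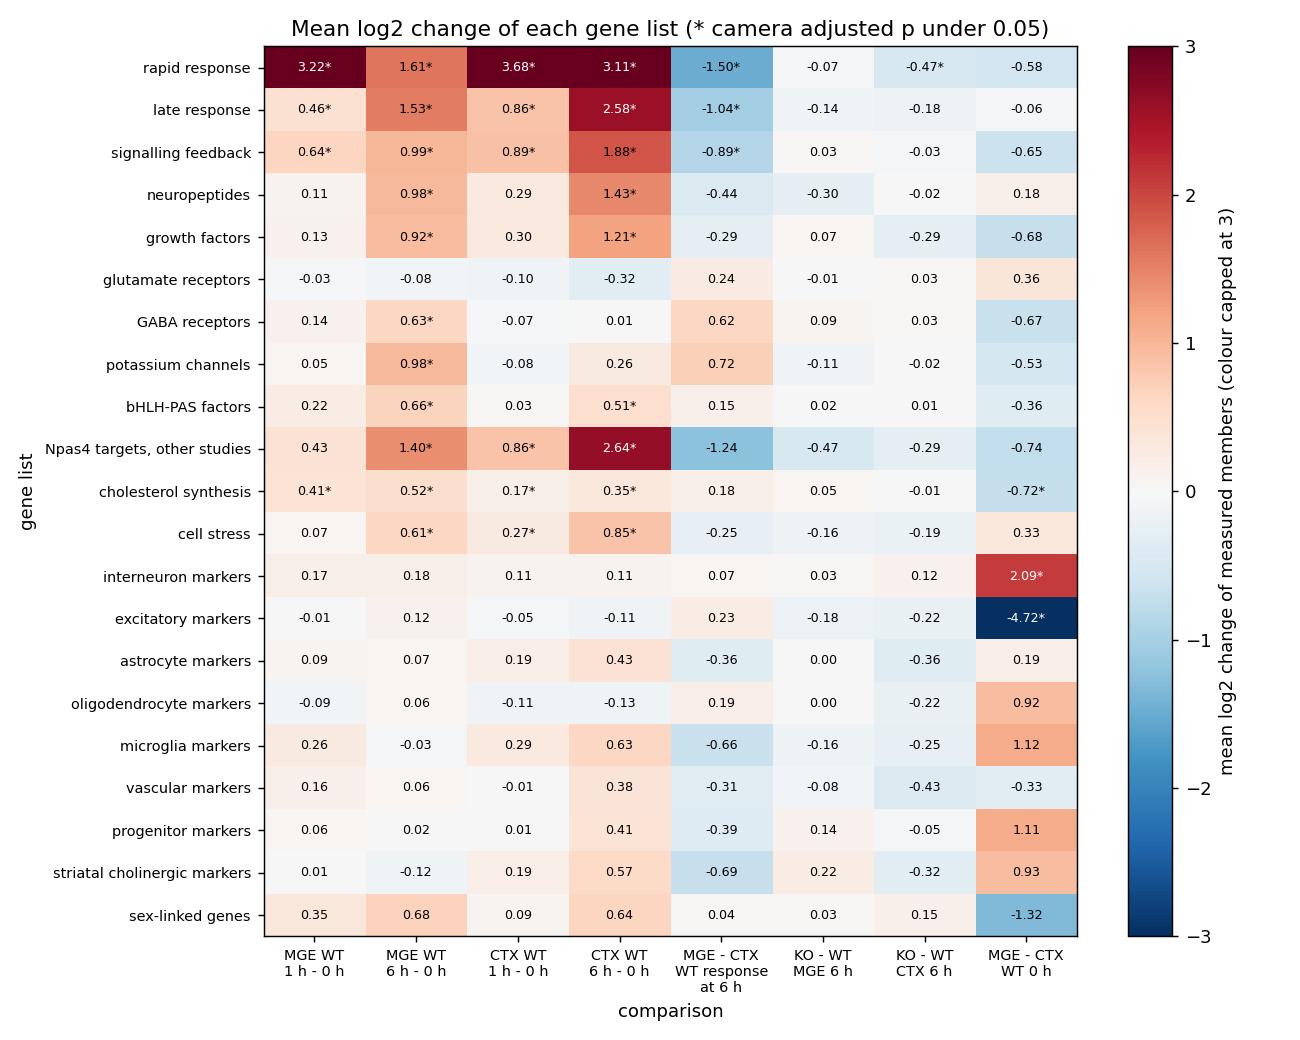
Mean log2 change of 21 gene lists (vertical) in 8 comparisons (horizontal) as colour capped at 3, with a star where the camera adjusted p was under 0.05. The rapid response list stood at 3.22 in MGE and 3.68 in CTX cultures at 1 h, and the excitatory markers at -4.72 in MGE against CTX.

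KO was compared with WT at each time to find genes whose level depended on Npas4. In MGE cultures at 6 h 4 genes were called, each lower in KO, and with the replicate block 10 were called, each lower. Npas4 was lower by 4.05-fold (log2 -2.02 ± 0.25, SE, n = 2 per group, adjusted p = 0.0043) and Adam11, a membrane protein of the ADAM family, by 3.41-fold (-1.77 ± 0.23, adjusted p = 0.0065). Zfyve28 was lower by 2.37-fold (-1.25 ± 0.15, adjusted p = 0.0043) and Osgin2 by 2.33-fold (-1.22 ± 0.14, adjusted p = 0.0043). Nptx2 (-1.53 ± 0.60, adjusted p = 1) and Bdnf (-0.79 ± 0.45, adjusted p = 1) did not pass. Without MGE WT 6 h repeat 1 none of the 4 passed (-1.65, -1.78, -1.17 and -1.01 in that order), nor without MGE KO 6 h repeat 2 (-1.88, -1.60, -1.23 and -1.19). Adam11 also did not pass without MGE WT 6 h repeat 2 (-1.76). With a separate fit per cell type Npas4, Adam11 and Osgin2 did not pass. At 1 h 3 genes were lower in KO, Npas4 by 21.8-fold (-4.45 ± 0.25, adjusted p = 4.2e-07), Mup10 by 3.27-fold (-1.71 ± 0.26, adjusted p = 0.04) and 1 Riken gene. Only Npas4 passed without MGE WT 1 h repeat 1, MGE WT 1 h repeat 2 or MGE KO 1 h repeat 1, where Mup10 stood at -1.64, -1.78 and -1.52. Mup10 also did not pass without MGE KO 1 h repeat 2 (-1.90). At 0 h limma called 0 genes, with 2598 at an unadjusted p under 0.05. The 0 calls became 3878 without MGE WT 0 h repeat 1, and 1 without MGE WT 0 h repeat 2 or MGE KO 0 h repeat 1, and Npas4 stood at -0.26 ± 0.25 (adjusted p = 0.54).

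In CTX cultures at 6 h 6 genes were lower in KO, Npas4 by log2 -4.00 ± 0.25 (SE, n = 2 per group, adjusted p = 1.8e-06). Cdt1, a DNA replication licensing factor, was lower by 3.66-fold (-1.87 ± 0.27, adjusted p = 0.024) and Gli2, a transcription factor of hedgehog signalling, by 2.99-fold (-1.58 ± 0.19, adjusted p = 0.0048). Slc30a1, a zinc exporter, was lower by 2.04-fold (-1.03 ± 0.16, adjusted p = 0.031), Bid, a pro-apoptotic BCL2 family member, by 1.79-fold (-0.84 ± 0.12, adjusted p = 0.025) and Hsd17b10, a mitochondrial dehydrogenase, by 1.57-fold (-0.65 ± 0.11, adjusted p = 0.047). Nptx2 (-0.80 ± 0.60), Arc (-0.67) and Bdnf (-0.34) each had an adjusted p of 1. Under the replicate block 35 genes were lower and 3 higher, and with a separate fit per cell type Gli2, Slc30a1, Bid and Hsd17b10 did not pass. The 6 calls became 129 without CTX WT 6 h repeat 1 (78 higher and 51 lower), 2 without CTX KO 6 h repeat 1 and 3 without CTX KO 6 h repeat 2. Gli2 did not pass without either KO array (-1.60 and -1.57), nor did Cdt1 (-1.85 and -1.90), Slc30a1 (-1.07 and -0.98), Bid (-0.87 and -0.80) or Hsd17b10 (-0.59 and -0.70). Without CTX WT 6 h repeat 2, Cdt1 (-1.67), Slc30a1 (-0.81), Bid (-0.70) and Hsd17b10 (-0.58) did not pass.

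At 1 h in CTX cultures Npas4 alone was called (33.7-fold lower in KO, log2 -5.07 ± 0.25, SE, n = 2 per group, adjusted p = 6.7e-08), and 2 genes with the replicate block, while Bdnf stood at 0.19 and Nptx2 at -0.14. At 0 h limma called 0 genes (49 at an unadjusted p under 0.05) and 2 with the replicate block, and Npas4 stood at -0.06. The list of Npas4 targets from other studies was not called in KO against WT at 6 h in either cell type. Its mean log2 level at 6 h was 10.08 and 9.91 in MGE WT and 9.60 and 9.46 in MGE KO arrays. In CTX cultures it was 12.14 and 11.82 in WT and 11.87 and 11.51 in KO arrays. The rapid response list had a lower mean in CTX KO at 6 h, with Npas4 the 1 member called, also over the list alone (mean -0.47, median -0.15, camera adjusted p = 0.00028, adjusted p = 0.41 with an estimated correlation). Without Npas4, an alternative chosen after seeing the data, its mean was -0.30 (adjusted p = 0.046). It did not pass without CTX KO 6 h repeat 1 (adjusted p = 0.38) or CTX WT 6 h repeat 2 (adjusted p = 0.71). The stress list had a lower mean in CTX KO at 1 h with no member called either way, Chac1 at -1.35 ± 0.51 and Trib3 at -0.78 ± 0.49 (mean -0.33, adjusted p = 0.032, adjusted p = 0.81 with an estimated correlation). It did not pass without CTX WT 1 h repeat 1 (adjusted p = 0.052) or CTX KO 1 h repeat 2 (adjusted p = 0.99).

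With the replicate block further lists passed in CTX KO against WT, each with no member called either way and none passing with the block and an estimated correlation (adjusted p from 0.32 to 0.75). At 0 h these were microglia (mean 0.28, adjusted p = 0.00019), astrocyte (-0.28, adjusted p = 0.0084) and oligodendrocyte markers (-0.27, adjusted p = 0.0055). At 1 h they were feedback (0.08, adjusted p = 0.04), interneuron (0.10, adjusted p = 0.04), astrocyte (-0.30, adjusted p = 0.04) and microglia markers (-0.25, adjusted p = 0.039). At 6 h they were growth factors (-0.29, adjusted p = 0.035) and vascular markers (-0.43, adjusted p = 0.01).

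**Figure D4:**
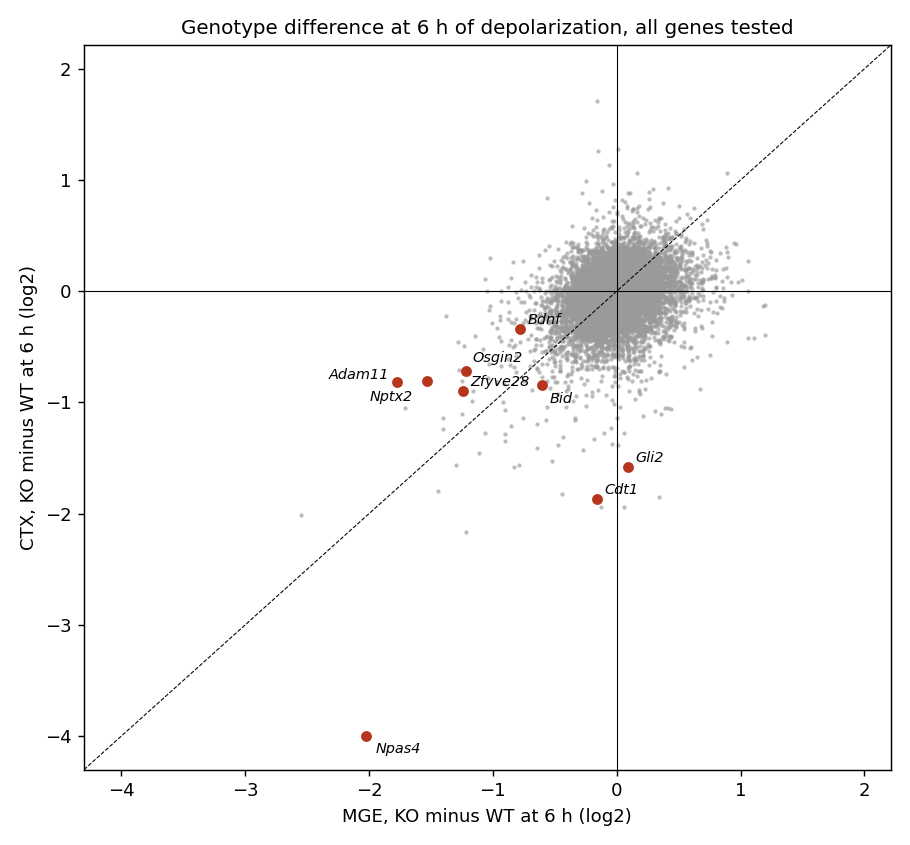
KO minus WT log2 difference at 6 h for each of 12378 genes, MGE on one axis and CTX on the other. Npas4 lies lowest in CTX (-4.00, and -2.02 in MGE), with Adam11 (-1.77 in MGE) and Cdt1 (-1.87 in CTX) among the labelled genes.

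Whether the response itself depended on genotype was tested by an interaction. Npas4 rose less in KO at 1 h by 18.3-fold in MGE cultures (log2 -4.19 ± 0.35, SE, n = 2 per group, adjusted p = 0.0001) and by 32.2-fold in CTX cultures (-5.01 ± 0.35, adjusted p = 9.3e-06), and at 6 h by 15.3-fold in CTX cultures (-3.94 ± 0.35, adjusted p = 0.00023). It was the only gene called in each. With a separate fit per cell type the MGE difference at 1 h was the same in size and did not pass (adjusted p = 0.21, against 9.4e-06 to 0.0015 under the other alternatives). In MGE cultures at 6 h limma called 0 genes (190 at an unadjusted p under 0.05), with Npas4 at -1.76 ± 0.35 (adjusted p = 0.58), Nptx2 at -1.32 ± 0.85 (adjusted p = 1) and Bdnf at -0.60. The 0 calls became 693 without MGE WT 0 h repeat 1, and 1 without its repeat 2 or MGE KO 6 h repeat 1. Counts became 2 without MGE WT 0 h repeat 1 at 1 h in MGE cultures and 2 without CTX WT 0 h repeat 1 at 6 h in CTX cultures.

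For lists, the rapid response mean was below 0 in the interaction in CTX cultures at 6 h, with Npas4 the 1 member called, also over the list alone (mean -0.50, adjusted p = 2.9e-07, adjusted p = 0.36 with an estimated correlation). The mean was -0.33 without Npas4 (adjusted p = 0.00091). The list did not pass without CTX KO 6 h repeat 1 (adjusted p = 0.075) or CTX WT 6 h repeat 2 (adjusted p = 0.26). At 1 h in CTX cultures the microglia markers (mean -0.53, adjusted p = 0.0012) and the glutamate receptors (mean 0.05, adjusted p = 0.04) passed with no member called either way, each with adjusted p = 0.73 with an estimated correlation. The microglia markers did not pass without CTX WT 1 h repeat 1 (adjusted p = 0.33) or CTX KO 1 h repeat 2 (0.45), and the glutamate receptors without either of these (0.15 and 0.33), CTX KO 0 h repeat 1 (0.41) or CTX WT 0 h repeat 2 (0.37). With the replicate block, late response (mean 0.11, adjusted p = 0.029) and vascular markers (-0.23, adjusted p = 0.047) also passed at 1 h in CTX cultures (adjusted p = 0.30 and adjusted p = 0.60 with the block and an estimated correlation). At 6 h microglia (-0.52, adjusted p = 2.2e-05), vascular (-0.43, adjusted p = 0.0071) and striatal or cholinergic markers (-0.39, adjusted p = 0.028) did so (adjusted p = 0.35, adjusted p = 0.42 and adjusted p = 0.42 with the block and an estimated correlation).

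Most genes that responded in WT cultures also responded in KO cultures. Of the WT calls, 50 of 71 in MGE cultures at 1 h, 1753 of 3128 in MGE cultures at 6 h, 97 of 107 in CTX cultures at 1 h and 3832 of 4362 in CTX cultures at 6 h were also called in KO arrays. These KO counts were computed after seeing the data, and KO totals were 55, 2118, 136 and 4482.

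Induced genes, those that rose at least 2-fold in WT cultures, were tested for lower levels in KO. At 6 h in MGE cultures 5 of 517 were lower in KO when adjusted over the set alone, and 1 over all genes. Besides Npas4 and 1 Riken gene these were Lmo2, a transcriptional adaptor (log2 change of 2.14 in WT and -0.79 in KO, KO minus WT level -2.55 ± 0.48, SE, n = 2 per group, adjusted p = 0.017), Tmem94 (1.04 and -0.45, level -1.28 ± 0.24, adjusted p = 0.017) and Wif1, a secreted Wnt inhibitor (2.43 and 1.52, level -0.88 ± 0.17, adjusted p = 0.018). These 3 names were chosen after their values were seen. Lmo2 did not pass without MGE KO 6 h repeat 2 (-2.02), nor Tmem94 without either KO array at 6 h (-1.18 and -1.38), nor Wif1 without MGE KO 6 h repeat 2 (-0.73) or MGE WT 6 h repeat 2 (-0.64). Lmo2 and Tmem94 were not in the induced set without MGE WT 6 h repeat 1 (-2.07 and -1.16) or MGE WT 0 h repeat 2 (-2.55 and -1.28). With the replicate block 23 of 560 induced genes in MGE cultures at 6 h were lower in KO over the set alone. They included Nptx2 (level -1.53, limma adjusted p = 0.013) and Bdnf (level -0.79, adjusted p = 0.049). At 6 h in CTX cultures 16 of 629 were lower and 2 higher over the set alone (27 lower with the replicate block), and 3 lower over all genes. Besides Npas4, Cdt1 and Gli2 they included Csrnp1, a nuclear protein (3.77 in WT and 2.19 in KO, level -1.55 ± 0.31, adjusted p = 0.012), Sertad1 (3.78 and 1.74, level -2.16 ± 0.50, adjusted p = 0.029) and Osgin2 (1.39 and 0.49, level -0.72 ± 0.14, adjusted p = 0.012), also named after their values were seen. Csrnp1 and Sertad1 did not pass without CTX KO 6 h repeat 1 (-1.59 and -2.18) or 2 (-1.51 and -2.13) or CTX WT 6 h repeat 2 (-1.32 and -1.96), nor Osgin2 without CTX KO 6 h repeat 1 (-0.64). At 1 h Npas4 alone was lower, among 39 induced genes in MGE and 60 in CTX cultures. The rise itself was tested at 6 h by the genotype interaction, adjusted over the set alone. It was smaller in KO for 0 of 517 genes in MGE and 3 of 629 in CTX cultures. With the replicate block these were 3 of 560 and 8 of 690.

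As a whole the induced sets rose about as much in KO as in WT cultures, with a lower median in MGE at 6 h. The median KO minus WT log2 change was -0.02 in MGE and 0.02 in CTX cultures at 1 h, and -0.44 in MGE (0 in repeat 1 and -0.78 in repeat 2) and -0.01 in CTX cultures at 6 h. In MGE cultures at 6 h the KO minus WT level itself had a median of 0.12, and 33.1% of the set was lower in KO. Because the sets were chosen on WT arrays, chance alone places WT high. Sets chosen on the mean of both genotypes had 2 of 379 lower at 6 h in MGE and 5 of 664 in CTX cultures. The MGE median was then -0.27. With the replicate block 6 of 384 were lower in MGE and 13 of 672 in CTX cultures. Nptx2 was among these 6 (level -1.53, limma adjusted p = 0.02) and Bdnf was not. These sets required a mean rise of at least 2-fold over both genotypes. Lmo2, Tmem94, Cdt1, Gli2 and Osgin2 fell short of it, having risen little or fallen in KO, so they were not tested there. Without the block Npas4, Wif1 in MGE and Csrnp1 in CTX cultures were among those lower, and Sertad1 was not. With the block Sertad1 was also among those in CTX cultures (-2.16, adjusted p = 0.017). The 5 in MGE cultures became 8 without MGE WT 0 h repeat 1 or MGE WT 6 h repeat 2, 3 without MGE WT 6 h repeat 1 and 1 without MGE KO 6 h repeat 2. The MGE median at 6 h was -1.05 without MGE WT 0 h repeat 1 and -0.17 without its repeat 2, and at 1 h it was -1.10 without repeat 1. The 16 in CTX cultures became 46 without CTX WT 6 h repeat 1, 29 without its repeat 2 and 5 without CTX KO 6 h repeat 1. The 1 at 1 h became 2 without MGE WT 0 h repeat 1 in MGE cultures and 2 without CTX WT 1 h repeat 1 in CTX cultures.

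The effect of genotype at 6 h was compared between the cell types. Npas4 was reduced less in MGE than in CTX cultures, by 1.98 ± 0.35 on the log2 scale, which did not pass (SE, n = 2 per group, adjusted p = 0.36, and 0.03 with the replicate block), and Nptx2 (-0.73) and Bdnf (-0.45) did not pass. Limma called 0 genes, with 154 at an unadjusted p under 0.05, and 3 with the block. The rapid response list had a mean of 0.41 toward MGE with no member called, and 1 over the list alone (adjusted p = 1.6e-05, adjusted p = 0.35 with an estimated correlation). Without Npas4 the mean was 0.33 (adjusted p = 0.0015). It did not pass without CTX KO 6 h repeat 1 (adjusted p = 0.16) or CTX WT 6 h repeat 2 (adjusted p = 0.55). With the block, growth factors (mean 0.35, adjusted p = 0.007), vascular (0.35, adjusted p = 0.026) and striatal or cholinergic markers (0.54, adjusted p = 0.0059) also passed (adjusted p = 0.14, adjusted p = 0.54 and adjusted p = 0.38 with the block and an estimated correlation). KO minus WT differences correlated between the cell types across genes at r = 0.13 at 0 h, 0.32 at 1 h and 0.33 at 6 h (rho = 0.19, 0.38 and 0.31).

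Averaged over times and cell types, 9 genes were lower in KO and none higher. Npas4 was 6.25-fold lower (log2 -2.64 ± 0.10, SE, n = 12 arrays per genotype, adjusted p = 2.2e-09). The 12 arrays are 2 repeats at each time and cell type. Same-numbered arrays deviated together (median r of 0.61 in MGE and 0.37 in CTX cultures). They may therefore not be independent, and the errors and p-values of this comparison may be too small. Adamts5, an extracellular protease, was 1.45-fold lower (-0.53 ± 0.07, adjusted p = 0.016), Slc7a4, of an amino acid transporter family, 1.60-fold lower (-0.68 ± 0.11, adjusted p = 0.046) and Adam11 1.54-fold lower (-0.62 ± 0.10, adjusted p = 0.038). Zfyve28 (-0.41 ± 0.06), Xylb, a xylulokinase (-0.37 ± 0.06), Bid (-0.30 ± 0.05), Hsd17b10 (-0.27 ± 0.04) and 1 gene with a predicted name completed the 9. Npas4, Adamts5, Bid, Slc7a4 and Xylb were lower in KO in 6 of 6 combinations of time and cell type, and Adam11, Hsd17b10 and Zfyve28 in 5 of 6. The genes were chosen on the mean of these same combinations, so the counts are not separate support. Nptx2 (-0.53 ± 0.24, adjusted p = 0.20) and Bdnf (-0.21, adjusted p = 0.47) did not pass, and no list passed. With the replicate block 28 genes were lower and 3 higher. The 9 calls became 3205 without MGE WT 0 h repeat 1, and 17 and 16 without CTX WT 6 h repeat 1 or 2. They became 8 without MGE KO 0 h repeat 1, 11 without MGE WT 1 h repeat 2, 7 and 9 without CTX KO 1 h or 6 h repeat 2, 4 without MGE WT 0 h repeat 2, and 1 to 3 without each of the other 16 arrays. Npas4 passed without each array.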

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

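Of the tests below, the comparison of splits with balanced replicate numbers, the tests of the MGE WT 0 h array, and the cyclic loess, MGE and CTX tests of zinc finger genes were chosen only after the result was seen.

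Several results were singled out because an effect differed between groups in an interaction test. The response to depolarization differed between KO and WT for 1 gene in MGE cultures at 1 h, 1 in CTX cultures at 1 h and 1 in CTX cultures at 6 h, each time Npas4. In CTX cultures the lists that differed between genotypes were the glutamate receptors (0.05) and microglia markers (-0.53) at 1 h and the rapid response genes (-0.50) at 6 h, as mean log2 differences. Between MGE and CTX cultures the response differed for 2 genes at 1 h and 1350 at 6 h. At 1 h the lists were rapid response (-0.45), late response (-0.41), feedback (-0.26) and cholesterol (0.24), and at 6 h they were rapid response (-1.50), late response (-1.04) and feedback (-0.89). Among single genes at 6 h, Bdnf (-3.61), Npas4 (-2.73), Arc (-3.65) and Egr1 (-2.70) responded less in MGE cultures. The genotype effect at 6 h differed between cell types for the rapid response list (0.41). None of these lists passed with an estimated correlation.

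Probe sets with no gene symbol, or with several, lie outside the comparisons by gene and also responded. Of 3618 such probe sets tested, depolarization changed 97 at 1 h and 749 at 6 h in MGE WT cultures, and 328 at 1 h and 1192 at 6 h in CTX WT cultures. Some also differed by genotype. In MGE cultures 7 were lower in KO at 0 h, 12 at 1 h and 0 at 6 h. In CTX cultures 0, 0 and 1 were lower at these times, and averaged over times and cell types 9 were lower. The genotype interaction in MGE cultures at 6 h called 1, with a higher change in KO (log2 2.36). Which transcripts these probe sets measure was not settled.

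The first pattern weighed is the set of 9 genes lower in KO when averaged over times and cell types. Of 100 splits of the arrays within each cell type and time, the real one included, 11 gave at least as many genes, so chance is not excluded, and the highest other split gave 642, which points to a structure of the samples beyond genotype. Among 100 splits with balanced replicate numbers 1 gave as many, the real one, and the highest other gave 5. Both kinds of split reassigned genotype separately at each time. The real grouping keeps each genotype and repeat on one side at every time, and some of these differed lastingly, as sex-linked genes did in MGE arrays. The splits therefore cannot tell genotype from a lasting difference between cultures. DNA flanking the targeted locus is argued against, since 0 of the 8 genes other than Npas4 lie within 20 Mb of it. A different sex makeup of KO and WT cultures stays open, with Xist higher in KO by 0.71 and the mean of Y-linked genes at -0.06, and so does an effect of genotype. The Xist difference lay in MGE cultures, where WT repeat 2 was at 8.25 to 10.05. In CTX cultures Xist was at 12.06 to 12.79 in KO and 12.29 to 12.85 in WT arrays.

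The second pattern is the distance between the MGE WT 0 h arrays, 1507 genes over 2-fold apart. Degraded RNA in repeat 2 is argued against by the 3' minus 5' log2 difference of the Gapdh control probe sets, 0.68 in that array and 0.54 to 0.70 in the other 23. A lower share of neurons stays open, since interneuron markers (11.05, against 11.3 to 11.43) and GABA receptors (9.89, against 10.3 to 10.87) were low and 2 of 5 lists of other cell types were above the other 5 MGE arrays of repeat 2, but astrocyte and progenitor markers were within their range and vascular markers (7.10) lay below it (7.17 to 7.36) by less than their SD of 0.08. A wrong time label is argued against by the rapid response list, 7.91 in that array, 7.93 in the 3 other MGE arrays at 0 h and 11.05 in those at 1 h. No biological explanation was tested, and other handling differences of that culture stay open.

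The third pattern is the fall of 309 genes with Zfp symbols at 6 h, of which 176 fell and 19 rose in CTX WT cultures (57% fell, against 23.9% of other genes) and 71 fell and 16 rose in MGE WT cultures (23% against 15.6%). Low signal of these probe sets is argued against in KO arrays, where at most 13 of 10000 gene sets matched for signal had as low a median, and in CTX WT arrays (0), but it stays open in MGE WT arrays, where 111 sets did, above the limit of 100. A fall limited to WT arrays is argued against by the separate KO arrays, where the median was -0.59 in CTX and -0.20 in MGE cultures, with 58 fallen and 6 risen in MGE (13 of the 10000 sets as low); the limit set beforehand for MGE lay beyond its WT median, and so asked for a larger fall than the one to be explained. Scaling between arrays could account for the MGE fall at 6 h, where the median was -0.21 before and -0.09 after cyclic loess, but is argued against as the whole cause in CTX cultures, where it was -0.75 before and -0.67 after. At 1 h, for which no limit was set, the median was already -0.20 in MGE WT, -0.18 in MGE KO, -0.23 in CTX WT and -0.25 in CTX KO arrays. In each of these 0 of 10000 matched sets were as low, which argues against low signal as the cause at 1 h. After cyclic loess the 1 h median was -0.14 in MGE WT and in MGE KO arrays. Faster loss of short-lived transcripts after depolarization is an untested biological explanation.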

How the results depend on the processing

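KO arrays in place of WT arrays, the rapid response list without Npas4, and the block with an estimated correlation were chosen only after the results were seen. Under the mean of probe sets, no filter, cyclic loess, limma-trend, the replicate block and separate fits, no list or named gene that passed reversed and passed. Of 443 calls of named genes, 429 were kept with no filter, 433 with cyclic loess, 438 with limma-trend and 436 with the replicate block, as were 401 of 429 with the mean of probe sets and 254 of 302 with separate fits. Of 62 list calls, 58, 55, 58, 61 and 61 were kept with the mean of probe sets, no filter, loess, limma-trend and the block, 46 of 51 with separate fits, 9 with an estimated correlation and 24 with the block and that estimate.

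Counts of genes moved by over 1.5 times as follows, and the cause was not tested. Separate fits per cell type gave 58 for CTX at 1 h, 1, 2 and 3 for KO against WT in MGE at 1 h, MGE at 6 h and CTX at 6 h, 0 for the genotype interaction in MGE at 1 h (Npas4 at -4.19 did not pass), and 14 induced genes lower in KO in MGE at 6 h. The mean of probe sets gave 14 and 16 for KO against WT at 6 h in MGE and CTX, 21 averaged, and 10 induced genes in CTX at 6 h. With the replicate block KO against WT gave 10 in MGE at 6 h, 2, 2 and 38 in CTX at 0, 1 and 6 h and 31 averaged, the cell type by genotype interaction gave 3, and induced genes 23 in MGE (among them Nptx2 at -1.53 and Bdnf at -0.79) and 27 in CTX at 6 h. With no filter KO against WT gave 14 in CTX at 6 h, the genotype interaction in MGE at 6 h 2, the cell type interactions 1 for depolarization at 1 h and 1 for genotype, and induced genes 14 in MGE at 6 h. Cyclic loess gave 13 and limma-trend 13 for KO against WT in CTX at 6 h, and limma-trend 1 for the cell type by depolarization interaction at 1 h and 3 induced genes in MGE at 6 h. With sets chosen on the mean of genotypes, 2 induced genes were lower in MGE and 5 in CTX at 6 h, with medians of 0.08 in CTX at 1 h and 0.04 at 6 h, and with no fold minimum 9 in MGE at 6 h.

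Leaving out 1 array leaves a group with 1, which is assumed to vary like the other groups. Counts then ranged from 21 to 1813 for MGE at 1 h, 1103 to 5248 at 6 h and 485 to 1091 for 6 against 1 h, and from 38 to 93, 3050 to 3938 and 2107 to 3541 for the same in CTX. For KO against WT they ranged from 0 to 3878, 1 to 2 and 0 to 5 in MGE and 0 to 0, 1 to 1 and 2 to 129 in CTX at 0, 1 and 6 h, and from 1 to 3205 averaged. Genotype interactions ranged from 1 to 2 and 0 to 693 in MGE and 1 to 1 and 1 to 2 in CTX at 1 and 6 h, the cell type by depolarization interaction from 1 to 551 at 1 h and 539 to 3901 at 6 h, the cell type by genotype interaction gave 0, and MGE against CTX 5544 to 8319. The counts of 1813, 5248, 3878, 3205, 693, 551 and 3901 came without MGE WT 0 h repeat 1, and the 129 without CTX WT 6 h repeat 1. Induced genes lower in KO ranged from 1 to 2 and 1 to 8 in MGE and 1 to 2 and 5 to 46 in CTX at 1 and 6 h. Medians of their KO minus WT log2 change ranged from -1.10 to -0.01 and -1.05 to -0.17 in MGE and from -0.22 to 0.21 and -0.22 to -0.01 in CTX at 1 and 6 h. List calls ranged from 53 to 74 and named genes from 385 to 441. In MGE cultures correlations between same-numbered arrays ran from -0.23 to 0.86 (median 0.61). Under KO arrays in place of WT arrays the depolarization counts were 55 and 2118 in MGE and 136 and 4482 in CTX.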

Other observations

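The comparison below of KO and WT at 6 h averaged over cell types, and its splits, were chosen only after the data were seen. It called 34 genes, each lower in KO (75 with the replicate block, 73 of them lower), with 651 at an unadjusted p under 0.05. At 0 h limma called 0 genes, with 702 at an unadjusted p under 0.05. Lmo2 was 4.86-fold lower (log2 -2.28 ± 0.34, SE, n = 4 arrays per genotype, adjusted p = 0.0068), and Osgin2 (-0.97 ± 0.10), Adam11 (-1.30 ± 0.17), Zfyve28 (-1.07 ± 0.11), Csrnp1 (-1.17 ± 0.22) and Oxtr, the oxytocin receptor (-0.69 ± 0.11), were lower, all named after their values were seen. Not all of these were induced. From 0 to 6 h in WT cultures Oxtr changed by -1.60 in MGE and -0.72 in CTX, and Zfyve28 by 0.22 and -1.12. The other named genes changed upward in both cell types. The 18 splits of the 6 h arrays are too few for a share under 0.05, with the real split at 34 and the highest other at 888. Among the 8 splits that balance replicate numbers, the highest other was at 0.

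Sex-linked genes differed between arrays of the same group. Xist log2 intensity was 8.25, 10.05 and 9.37 at 0, 1 and 6 h in MGE WT repeat 2, against 11.72, 10.79 and 11.99 in repeat 1, 11.31 to 12.41 in MGE KO arrays and 12.06 to 12.85 in CTX arrays. Eif2s3y, a Y-linked gene, was 9.38 to 9.87 in MGE KO repeat 1 and 10.65 to 12.04 in the other arrays. Between MGE and CTX cultures at 0 h Xist was lower in MGE by -2.42 ± 0.88 on the log2 scale (n = 2 per group, limma adjusted p = 0.026), and did not pass without MGE WT 0 h repeat 2 (-0.68), CTX WT 0 h repeat 1 (-2.53) or CTX WT 0 h repeat 2 (-2.30).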
